A study of Mus musculus with 24 samples.

How the data were processed

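Inguinal white adipose tissue (IWAT), the subcutaneous fat pad of the groin, was profiled by 3′ mRNA sequencing in 24 male C57BL/6J mice, 6 on each of 4 diets. The diets differed in the source of protein and in methionine. They were elemental amino acids with 0.86% methionine (elemental control), elemental amino acids with 0.17% methionine (elemental MR, for methionine restriction), intact casein (casein control, 0.86% methionine) and casein oxidized to destroy its methionine, with methionine returned to the level of the elemental MR diet (oxidized casein MR, 0.17% methionine). The mice started the diets at 5 weeks of age, stayed on them for 12 weeks and were killed at 4 months of age after a 4 h fast, per the labels. The labels' series design text speaks of the liver transcriptome, while the series title, the sample source and the protocol name IWAT, and the libraries are described here as IWAT. Each library is a separate mouse, per the mouse numbers in the labels. Sequencing batches, and which mice belonged to which of the cohorts that the labels mention for energy expenditure, were not given in the sources used here.

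The authors made a table of raw gene counts from 50 bp single-end reads of QuantSeq libraries, a kit that reads a short stretch at the 3′ end of each polyadenylated transcript, so a count does not grow with transcript length. The submitters' processing notes name R 3.4.3, DESeq2 1.18.1 and the genome builds GRCm38 and mm10, and the aligner, the counting program and its strand setting are not given in the sources used here. The deposited raw table holds whole-number counts for 16821 Ensembl genes, and its smallest gene total over the 24 libraries is 72 reads, a mean of 3 reads per library, so genes below that mean are not listed. The authors also deposited a normalized signal table, whose values equal the raw counts divided by a median-of-ratios size factor per library, to a largest relative difference of 5.6e-16. Every test used the raw counts. Library totals ran from 7468336 to 19868913 reads. Reads are PCR copies without molecular identifiers, so precision was taken from the spread between mice. No pair of libraries of a group agreed within counting error alone (smallest chi-square per degree of freedom 6.21), a limit that technical repeats could also exceed. All 24 were counted as separate samples because the labels give each its own mouse number. Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which gave a symbol for 16771 of the gene identifiers.

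Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the diet groups, which left 15176 genes and removed 1645, library totals were scaled by TMM, and a single model with 1 mean per diet was fitted to all 24 libraries with robust dispersions. Quasi-likelihood F tests (2-sided) gave the 5 comparisons: MR against control on elemental amino acids, MR against control on casein, the difference between these MR effects (interaction), casein control against elemental control, and oxidized casein MR against elemental MR. Adjusted p-values are Benjamini-Hochberg values over the 15176 genes with a threshold of 0.05, and are edgeR's unless another test is named. The standard error (SE) of a log2 fold change was derived from the fold change and its F statistic. Levels are CPM, with each library's total scaled by TMM, as mean ± SD of the 6 mice of a diet.

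Before the data were examined, 32 gene lists were fixed. They cover thermogenic beige and brown adipocyte genes, de novo lipogenesis and glyceride synthesis, lipolysis and fatty acid uptake, fatty acid oxidation, nuclear oxidative phosphorylation, the TCA cycle, mitochondrially encoded transcripts, ATF4 targets of amino acid stress, methionine and one-carbon metabolism, glutathione and NRF2 targets, white adipocyte identity, insulin signalling, cholesterol synthesis, ER stress, macrophage and inflammation genes, extracellular matrix, interferon response, proliferation, the circadian clock and immediate early genes. The other 12 hold markers of B cells, T cells, skeletal muscle, keratinocytes, ductal epithelium, hepatocytes, endothelium, adipose progenitors, smooth muscle, red blood cells, nerve, and granulocytes and mast cells. For each list the members past the threshold over all genes, and those past it when adjusted over the list alone, were counted. Lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, adjusted over the 32 lists, then with the correlation estimated per list, and with fry, which asks whether a list moved on balance in 1 direction. A list score is the mean log2 CPM of its members in a library (prior count 2). Scores, the share of mitochondrial reads and 6 genes fixed in advance were compared with 2-sided exact permutation tests, adjusted over 45, 60 and 30 tests for process scores, marker scores and genes. For the interaction, the protein source was permuted within each methionine level. That test is exact only if the protein source has no effect at either methionine level.

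Genes named in the text were chosen by a rule fixed before the data were examined: among genes past the threshold with an average log2 CPM of at least 2 and a symbol that is not a clone name, the 8 largest rises and 8 largest falls (4 and 4 for the other comparisons), up to 4 members with the smallest p per list spoken of, and Ucp1, Fgf21, Lep, Fasn, Scd1, Asns and Psat1 throughout. The marker genes Alb and Acta1 and the clone-named gene 2810032G03Rik were chosen after their values were seen.

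The test was tested on simulated counts drawn from the real means, library sizes and dispersions of the 15176 genes with 200 genes changed. Each gene was drawn independently, without the differences in other tissues that move many genes of a real library together. The false calls therefore do not cover errors from such shared variation. For the elemental MR comparison edgeR recovered 10.4%, 46.3% and 81.8% of genes changed by 0.5, 1 and 2 on the log2 scale, with 5 false calls, and for the casein MR comparison 7.46%, 46.3% and 83.3%, with 4. For the interaction these shares were 0%, 35.8% and 71.2% with 0 false calls, for the controls 13.4%, 59.7% and 83.3% with 8, and for the MR diets 5.97%, 34.3% and 90.9% with 3. On the same simulated counts DESeq2 made 14 false calls between the controls and 13 in each other comparison. Limma voom made 4 for elemental MR, 2 for casein MR, 3 for the interaction, 8 for the controls and 4 for the MR diets. Alternatives fixed in advance were DESeq2 size factors and upper-quartile scaling in edgeR, DESeq2 1.42.0, limma voom with sample weights, no filter and a stricter filter (CPM of at least 2 in 6 libraries), fits of only the groups compared, the B and T cell score or the muscle score as covariate, a threshold of 0.01, and leaving out each library. Added after seeing the data were lymph node presence (B cell score of at least 4) as a term, fits within the libraries with and without it, leaving out the 2 libraries richest in muscle transcripts, and removing the mitochondrially encoded genes and Gm42418, a gene that overlaps ribosomal RNA sequence. Thinning all libraries to the reads of the smallest tested the effect of depth. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.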

Results

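The data were gene counts of IWAT from 24 male mice, 6 per diet, after 12 weeks on control (0.86% methionine) or methionine-restricted (MR, 0.17% methionine) diets whose protein was either elemental amino acids or casein, which was oxidized in the MR diet. The question posed by the series was how MR built on oxidized casein changes the transcriptome of this fat pad beside MR built on elemental amino acids. Library totals ran from 11937056 to 19868913 reads in elemental controls, 8360132 to 17129341 in elemental MR, 8023612 to 14662176 in casein controls and 7468336 to 16201962 in oxidized casein MR. The casein comparison pairs intact casein with oxidized casein, so casein oxidation and methionine level change together in it and in the difference between the MR effects. Mitochondrially encoded transcripts took between 15.1% and 36.2% of the reads of a library.

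The libraries differed in the other tissues they held. B cell markers, which mark the lymph node embedded in this pad, averaged 5.20 to 6.79 log2 CPM in 15 libraries and 0.34 to 3.24 in the other 9, and the first principal component of all genes, with 43% of the variance, separated these sets. Lymph node transcripts were present in 4 of 6 elemental controls, 5 of 6 elemental MR, 4 of 6 casein controls and 2 of 6 oxidized casein MR libraries. Acta1, actin of skeletal muscle, stood at 2946 CPM in elemental control 2 and 1239 CPM in elemental MR 2, against at most 166.3 CPM elsewhere. Alb, serum albumin, reached 5610 CPM in elemental control 6 and at most 864.7 CPM in the other libraries. None of the 60 exact permutation tests of the 12 marker scores between diets passed after adjustment (smallest adjusted p = 0.47, n = 6 per diet).

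**Figure D1:**
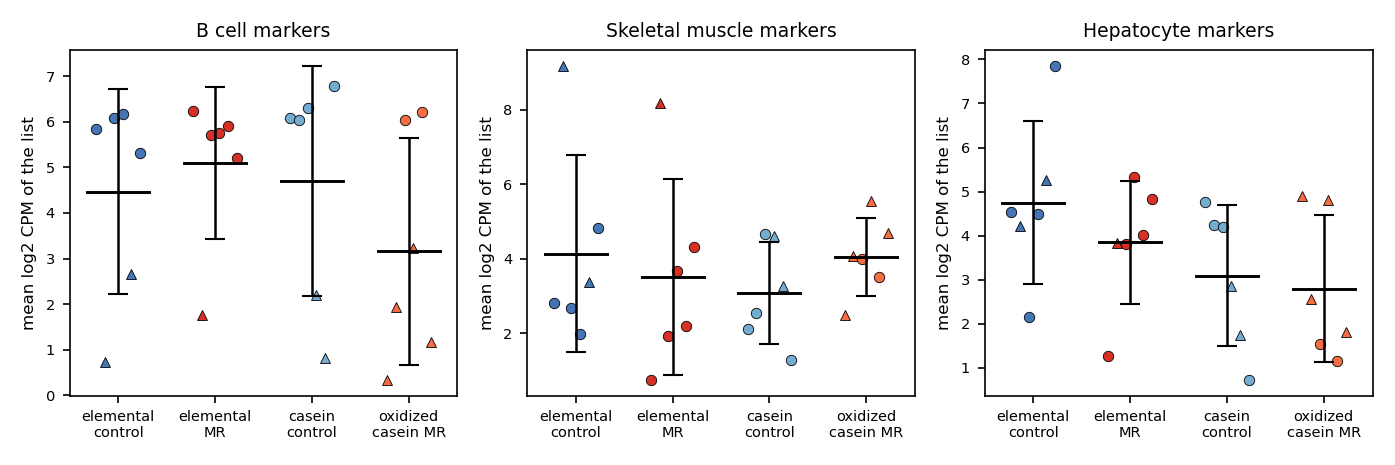
Mean log2 CPM of the B cell, skeletal muscle and hepatocyte marker lists (y axis) in the 6 libraries of each diet (x axis), with circles for libraries with lymph node transcripts, triangles for those without, and bars for the mean ± SD. B cell scores formed separate sets in every diet, muscle scores were highest in elemental control 2 (9.19) and elemental MR 2 (8.19), and the hepatocyte score was highest in elemental control 6 (7.86).

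With MR on elemental amino acids 33 genes rose and 4 fell. Slc25a34, a mitochondrial carrier, went from 5.78 ± 2.13 CPM to 44.7 ± 9.48 CPM (SD, n = 6 each; log2 fold change 2.96, SE 0.37, edgeR adjusted p = 0.000655). Dhrs9, a retinol dehydrogenase, rose 9.06-fold (SE 0.53 on the log2 scale), the bicarbonate cotransporter Slc4a4 3.19-fold (SE 0.29), and Slc25a42, the mitochondrial carrier of coenzyme A, 2.47-fold (SE 0.26). Gk, glycerol kinase, had a log2 fold change of 1.93 (SE 0.36, adjusted p = 0.0211). Clstn3 rose 2.31-fold, Slc25a20, the carnitine-acylcarnitine carrier, 2.04-fold, and Kcnk3, a potassium channel of brown adipocytes, 1.99-fold. The 4 genes that fell were Igfbp4, an insulin-like growth factor binding protein (2.37-fold lower, SE 0.21, adjusted p = 0.0106), Abi3bp (1.99-fold lower), Nucb2 (1.48-fold lower) and the clone-named gene 2810032G03Rik.

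Among the fixed lists, 3 of 25 thermogenic genes rose (Kcnk3, Gk and Slc25a20), and 9 did when adjusted over the list alone, with a median log2 fold change of 0.98. The list passed camera at the preset correlation (adjusted p = 7.7e-18) but not with an estimated correlation (adjusted p = 0.073). Its score per library was 6.12 ± 0.23 with MR and 5.17 ± 0.64 in controls (exact permutation p = 0.00649, adjusted p = 0.0292, n = 6 each). Ucp1, the uncoupling protein of thermogenic adipocytes, measured 480 ± 427 CPM in controls and 1840 ± 590 CPM with MR. It did not pass in edgeR (log2 fold change 1.94, SE 0.85, adjusted p = 0.424), whereas all 6 MR libraries lay above all 6 controls on the log scale (exact permutation p = 0.00216, adjusted p = 0.0216, n = 6 each). Of the 22 fatty acid oxidation genes, Slc25a20 and Crat, carnitine acetyltransferase (1.54-fold), rose, and 17 did adjusted over the list alone. This list passed with an estimated correlation too (adjusted p = 0.046). Etfdh (log2 fold change 1.02, SE 0.24, adjusted p = 0.0697) and Acot2 (1.09, SE 0.24, adjusted p = 0.0583) did not pass.

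No gene of nuclear oxidative phosphorylation passed over all genes, while 39 of 42 were higher adjusted over the list alone, with a median log2 fold change of 0.47. Uqcrfs1 of complex III had a log2 fold change of 0.70 (SE 0.21) and Cox4i1 of complex IV 0.48 (SE 0.15). For the TCA cycle these counts were 0 and 14 of 20, with a median of 0.51 and Idh3a at 0.85 (SE 0.20), and for mitochondrially encoded transcripts 0 and 6 of 8, with a median of 0.60 and mt-Nd1 at 0.65 (SE 0.21). All 3 lists passed camera at the preset correlation and fry (adjusted p = 0.035 for each), and none passed camera with an estimated correlation (adjusted p = 0.097 for each). The oxidative phosphorylation and TCA cycle scores were higher with MR by 0.49 and 0.558 and did not pass (exact permutation p = 0.0216, adjusted p = 0.0573 for each, n = 6 each). The share of mitochondrially encoded reads was 32.9% ± 2.73 with MR and 26.2% ± 3.97 in controls (exact permutation p = 0.0108, adjusted p = 0.0375, n = 6 each).

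The lipogenic list had 0 of 28 members past the threshold, over all genes or over the list alone, and a median log2 fold change of 0.03. Fasn, fatty acid synthase, stood at 6910 ± 1470 CPM with MR and 6170 ± 1740 CPM in controls, and Scd1, a fatty acid desaturase, had a log2 fold change of -0.23 (SE 0.20). Extracellular matrix genes had a median of -0.66 with 0 of 29 past the threshold over all genes and 14 lower over the list alone (Col3a1 -1.18, SE 0.34, and Col1a2 -0.95, SE 0.29). The median of the 27 macrophage genes was -0.59, with 0 past the threshold and 4 lower over the list alone (Adgre1 -0.86, Mrc1 -0.76). Markers of adipose progenitors had a median of -0.54, with 0 of 17 past the threshold and 7 lower over the list alone (Cd34 -0.85, Pdgfra -0.64). These 3 lists passed camera at the preset correlation but not with an estimated correlation (adjusted p = 0.21, 0.14 and 0.14). The extracellular matrix and macrophage scores did not pass either (exact permutation p = 0.0281 and 0.0173, adjusted p = 0.0603 and 0.0557, n = 6 each). Lep, leptin, measured 358 ± 248 CPM in controls and 100 ± 69.6 CPM with MR (edgeR adjusted p = 0.297; exact permutation p = 0.00866, adjusted p = 0.0371, n = 6 each). None of the 36 ATF4 targets passed over all genes or over the list alone, and Asns and Psat1, biosynthetic enzymes of asparagine and serine, had log2 fold changes of 0.04 (SE 0.19) and -0.36 (SE 0.31). Fgf21, a hormone known to rise in liver under MR, had 0 to 14 reads per library over the 24 libraries and was not tested. The count of 37 genes was 7 without elemental control 5 or elemental MR 6, 8 without elemental control 2 or 4 or elemental MR 4, 15 without elemental control 6, 57 without casein control 6 and 252 without elemental control 1. It was 8 without both muscle-rich libraries and 5 within the libraries with lymph node transcripts, while only 1 elemental MR library was without them. Counts with a larger share of lower genes were 166 with lymph node presence as a term (104 higher, 62 lower), 213 in DESeq2 (153 and 60) and 118 in limma voom (87 and 31).

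**Figure D2:**
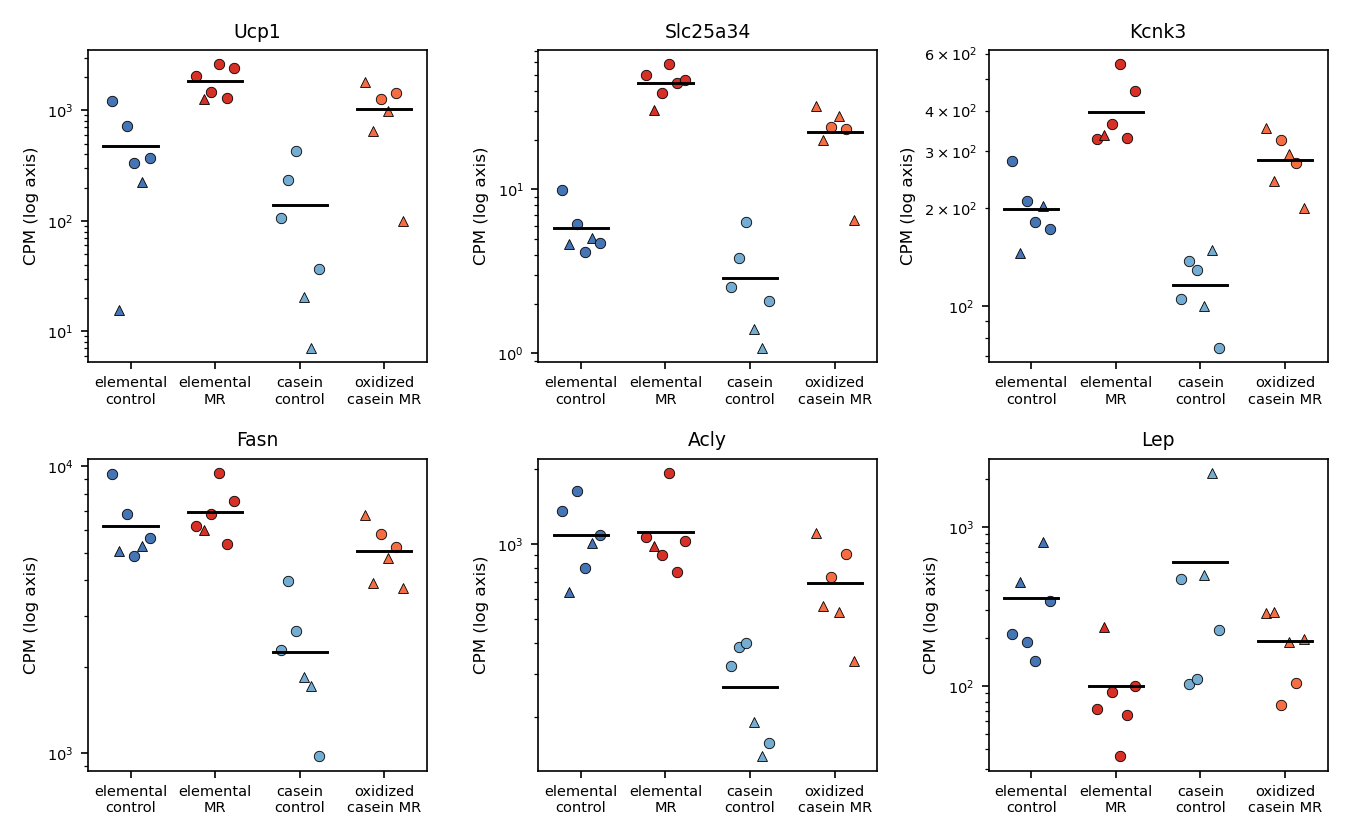
Levels of Ucp1, Slc25a34, Kcnk3, Fasn, Acly and Lep in CPM on a log axis (y) for the 6 libraries of each diet (x), with circles for libraries with lymph node transcripts, triangles for those without, and a line at the mean CPM of the diet. All 6 elemental MR libraries lie above all 6 elemental controls for Ucp1 and Slc25a34, and all 6 casein controls lie below all 6 elemental controls for Fasn (means 2250 and 6170 CPM).

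MR on oxidized casein raised genes of mitochondrial metabolism, thermogenesis and lipogenesis. Among named genes with an average log2 CPM of at least 2, the largest rises were in Lgr6, a receptor for R-spondins (15.8-fold, SE 0.77 on the log2 scale), Elovl3, a fatty acid elongase of brown fat (10.9-fold, SE 0.77), and Dhrs9 (9.12-fold, SE 0.57). Slc25a34 rose from 2.87 ± 1.95 CPM to 22.4 ± 8.81 CPM (SD, n = 6 each; log2 fold change 2.97, SE 0.38, edgeR adjusted p = 0.000592). Cox7a1, a cytochrome oxidase subunit, the prolactin receptor Prlr, Ppp1r3b, which targets a phosphatase to glycogen, and the mitochondrial carrier Slc25a48 rose between 4.25-fold and 4.47-fold. Of 579 genes that passed, 509 were higher and 70 lower. Among genes chosen in the same way, the largest falls were in the complement gene C6 (3.31-fold, SE 0.38), the tubulin Tuba1a (3.24-fold, SE 0.48), Ntm (2.77-fold), the amino acid transporter Slc7a8 (2.63-fold), Nedd9 (2.48-fold), Cyp2e1 (2.47-fold), Prtn3 (2.41-fold) and the inositol transporter Slc2a13 (2.32-fold).

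Nuclear oxidative phosphorylation genes rose together, with 39 of 42 past the threshold over all genes, 41 over the list alone, and a median log2 fold change of 0.75. Uqcrb of complex III rose 1.80-fold (SE 0.16 on the log2 scale), Atp5d of ATP synthase 1.68-fold (SE 0.14) and Ndufb10 of complex I 1.58-fold (SE 0.12). In the TCA cycle 18 of 20 rose (20 over the list alone; median 0.87), among them Idh3a (2.08-fold) and Ogdh (1.89-fold). Of the fatty acid oxidation genes 15 of 22 rose (19 over the list alone; median 0.84), led by Eci1 (2.04-fold), Crat (1.80-fold) and Decr1 (1.73-fold). Mitochondrially encoded transcripts rose in 6 of 8 cases (8 over the list alone), with mt-Nd1 2.02-fold and mt-Nd5 1.81-fold higher. Their share of reads was 27.9% ± 4.36 with MR and 18.8% ± 3.61 in controls (exact permutation p = 0.00433, adjusted p = 0.0216, n = 6 each). Thermogenic genes rose in 9 of 25 cases (18 over the list alone; median 1.24), among them Kcnk3 (2.43-fold, SE 0.19), Gk (3.20-fold, SE 0.36), Acot2 (2.19-fold) and Slc25a20 (2.28-fold). Ucp1 measured 140 ± 166 CPM in casein controls and 1040 ± 601 CPM with MR, with 5 of 6 MR libraries above all controls. It did not pass in edgeR (log2 fold change 2.89, SE 0.88, adjusted p = 0.0741) and passed the exact permutation test (p = 0.013, adjusted p = 0.0487, n = 6 each). In libraries with lymph node transcripts Ucp1 stood at 1261 and 1431 CPM with MR and at most 431.2 CPM in controls. In those without them it stood at 99.42 CPM or more with MR and at 7.121 and 20.48 CPM in controls.

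Lipogenic genes rose as well with MR on casein, in 15 of 28 cases over all genes and 24 over the list alone, with a median log2 fold change of 0.83. Fasn rose 2.25-fold, from 2250 ± 1030 CPM to 5060 ± 1150 CPM (SE 0.25 on the log2 scale, adjusted p = 0.00968), and Scd1 1.88-fold. Acaca, acetyl-CoA carboxylase, rose 2.36-fold, Insig1, a regulator of sterol and lipid synthesis, 2.28-fold, the pyruvate carboxylase gene Pcx 1.80-fold and Dgat1, which makes triglycerides, 1.70-fold. The 6 lists described for this comparison so far passed camera with an estimated correlation (adjusted p between 0.016 and 0.027) and fry. White adipocyte genes rose in 4 of 24 cases, namely Cfd, the adipokine adipsin (1.87-fold), Pck1 (1.70-fold), Adig (1.64-fold) and the insulin-responsive glucose transporter Slc2a4 (1.54-fold), with no call for the list at an estimated correlation (adjusted p = 0.69). Macrophage genes had a median of -0.46, with Cd68 lower (1.95-fold) as the only member of 27 past the threshold (adjusted p = 0.51 for the list with an estimated correlation), and extracellular matrix genes a median of -0.27 with 0 of 29 past it. In libraries without lymph node transcripts extracellular matrix scores were 6.234 to 6.719 with MR and 7.062 and 7.232 in controls. In those with them the scores were 5.811 and 5.896 with MR, within the control range of 5.682 to 6.462. Lep (601 ± 799 CPM in controls, 192 ± 90.6 CPM with MR, adjusted p = 0.199; log2 fold change -1.65, or -0.558 without casein control 5, which stood at 2195 CPM), Asns (log2 fold change 0.33, SE 0.19) and Psat1 (-0.07, SE 0.31) did not pass. Across left-out libraries Asns ran from 0.22 (oxidized casein MR 6) to 0.467 (casein control 5). Psat1 ran from -0.214 (casein control 3) to 0.309 (casein control 5). The count of 579 was 5 within the libraries with lymph node transcripts, of which the oxidized casein MR group had 2, 172 within those without (75 higher, 97 lower) and 1120 with lymph node presence as a term (689 and 431). It was 377 without casein control 1, 316 without casein control 6, 350 without oxidized casein MR 1, and 1968 in limma voom (1171 and 797).

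**Figure D3:**
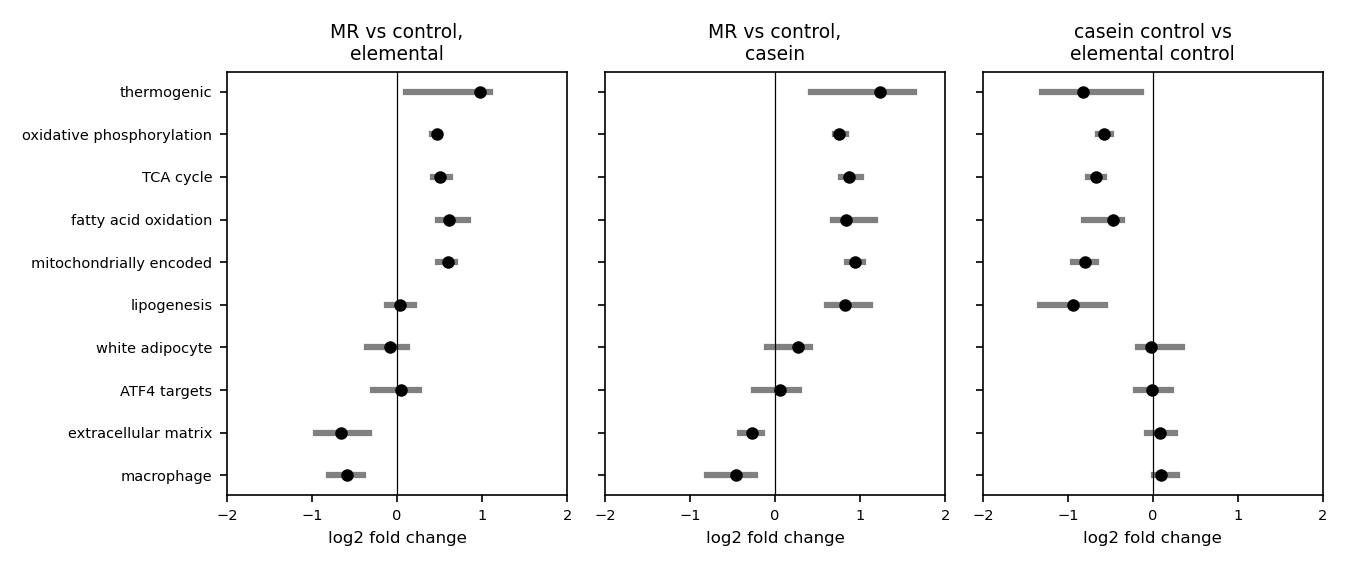
Log2 fold changes (x axis) of the members of 10 fixed lists in 3 comparisons, with a dot at the median and a grey bar from the lower to the upper quartile of the members. The lipogenic median is 0.03 for MR on elemental amino acids, 0.83 for MR on casein and -0.94 for casein controls against elemental controls, while the medians of the thermogenic and mitochondrial lists are above 0 in both MR comparisons.

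The MR effects on the protein sources, which share no libraries, overlapped. Of the 33 genes higher with MR on elemental amino acids, 29 were also called higher on casein, where independent lists would share 1.11 (Fisher's exact test, p = 2.87e-39), among them Dhrs9, Slc25a34, Gk, Slc4a4, Slc25a42, Clstn3, Slc25a20, Kcnk3 and Crat. Of the 4 lower genes, Igfbp4 was lower in both (0.0185 for independent lists, Fisher's exact test, p = 0.0183), and 0 genes were called in opposite directions. Fisher's test treats genes as independent, which they are not, so its p-values overstate the evidence for overlap. Among the 509 genes higher with MR on casein, 500 had the same sign on elemental amino acids and 361 of these had an unadjusted p under 0.05, and among the 70 lower genes 67 and 31 did. The median ratio of the elemental to the casein log2 fold change over the casein calls was 0.57. These genes were picked by their casein p-value, which inflates the casein fold changes. Across all 15176 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.25 and a Spearman rho of 0.25.

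No gene passed the test of the difference between the MR effects in edgeR, with 506 genes at an unadjusted p under 0.05. Independent genes without any difference would give 758.8, and these genes are not independent. DESeq2 called 2 genes and limma voom 0. Lipogenesis was the only list of 32 past the threshold with an estimated correlation, where 20 passed at the preset one. All 28 members had a larger MR effect on casein, with a median difference of 0.80 on the log2 scale, 0 past the threshold over all genes and 15 over the list alone. The list passed camera with an estimated correlation (adjusted p = 0.02) and fry (adjusted p = 0.03). Its score per library gave a difference of 0.83 (exact permutation p = 0.0239, adjusted p = 0.0598), which did not pass. Insig1 had a difference of 1.53 (SE 0.31, edgeR adjusted p = 0.703), Acss2, which makes acetyl-CoA from acetate, 0.99 (SE 0.26), Pcx 0.86 (SE 0.24), Fasn 1.01 (SE 0.36) and Scd1 1.14 (SE 0.28). Scd1 passed the permutation test of the difference (p = 0.000443, adjusted p = 0.0133) but not edgeR (adjusted p = 0.91). That permutation assumes no effect of protein source at either methionine level, while Scd1 differed between the controls (exact permutation p = 0.00433, adjusted p = 0.026). The thermogenic list had a median difference of 0.37 with an adjusted p of 0.68 at an estimated correlation, and Ucp1 a difference of 0.95 (SE 1.17), Lep 0.19 (SE 0.91), Asns 0.29 (SE 0.27) and Psat1 0.29 (SE 0.44). With lymph node presence as a term these differences were 2.04, -0.358, 0.0201 and -0.157, and none passed. Without that term, and with single libraries left out, they ran from 0.45 (elemental control 1) to 1.74 (casein control 3) for Ucp1, from -0.231 (elemental control 5) to 1.28 (casein control 5) for Lep, from 0.185 (casein control 6) to 0.426 (casein control 5) for Asns and from 0.122 (elemental control 5) to 0.67 (casein control 5) for Psat1. Nuclear oxidative phosphorylation genes had a median difference of 0.30 (adjusted p = 0.54 at an estimated correlation). Markers of other tissues had median differences of 1.82 for skeletal muscle (18 of 18 above 0), 1.53 for hepatocytes (19 of 19), 1.32 for red blood cells (6 of 9 higher over the list alone), -1.29 for B cells and -0.94 for T cells. None of these lists passed with an estimated correlation (adjusted p = 0.60, 0.70, 0.13, 0.54 and 0.56). Medians were 1.59 for ductal epithelium, 1.24 for keratinocytes and 0.424 for adipose progenitors, which did not pass either. Without elemental control 6 the ductal median was 0.972 and the keratinocyte median 0.609. The muscle median was -1.66 without elemental control 2 and 4.74 without elemental MR 2, and the hepatocyte median 0.0706 without elemental control 6. With single libraries left out the B cell median ran from -2.01 (oxidized casein MR 5) to -0.938 (casein control 6) and the T cell median from -1.60 (oxidized casein MR 3) to -0.501 (casein control 6).

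**Figure D4:**
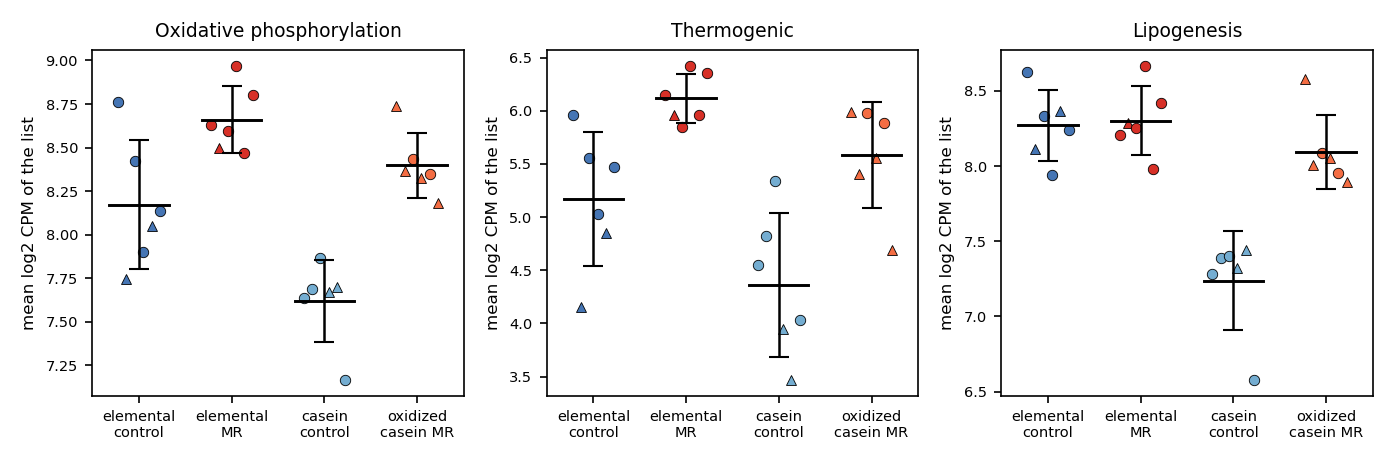
Mean log2 CPM of the nuclear oxidative phosphorylation, thermogenic and lipogenic lists (y axis) in the 6 libraries of each diet (x axis), with circles for libraries with lymph node transcripts, triangles for those without, and bars for the mean ± SD. Lipogenic scores were 8.27 ± 0.23 and 8.30 ± 0.23 on elemental amino acids, 7.24 ± 0.33 in casein controls and 8.10 ± 0.25 with oxidized casein MR.

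The control diets, equal in stated methionine, differed in lipogenic genes. In casein controls Slc2a5, the fructose transporter, was 6.70-fold lower than in elemental controls (SE 0.61 on the log2 scale, adjusted p = 0.0381), and Elovl6, an elongase of saturated fatty acids, 5.27-fold (SE 0.44). Acly, ATP citrate lyase, was 4.10-fold lower, from 1090 ± 362 CPM to 265 ± 116 CPM (SD, n = 6 each; SE 0.32), and Tmem79 3.55-fold (SE 0.34). Of 100 genes that passed, 98 were lower in casein controls, and the 2 higher were the interferon-induced Ifi27l2a (2.03-fold, adjusted p = 0.0484) and the semaphorin Sema5a (1.69-fold, adjusted p = 0.014). Of the 28 lipogenic genes 15 were lower, 22 over the list alone, with a median log2 fold change of -0.94. Insig1 was 2.78-fold lower, the citrate carrier Slc25a1 2.66-fold, Acss2 2.43-fold, Fasn 2.75-fold (SE 0.26, adjusted p = 0.00945) and Scd1 1.77-fold (adjusted p = 0.049). The list passed with an estimated correlation (adjusted p = 0.001). The scores of all 6 casein controls lay below those of all 6 elemental controls (difference -1.03, exact permutation p = 0.00216, the smallest that 6 against 6 allows, adjusted p = 0.0162).

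Markers of other tissues had lower medians in casein controls too, with 17 of 18 muscle markers (median -3.52), 16 of 19 hepatocyte markers (-2.29) and 6 of 9 red blood cell markers (-0.93) lower over the list alone and 0 over all genes in edgeR (adjusted p = 0.84, 0.47 and 0.19 with an estimated correlation). The muscle median was 0.162 without elemental control 2 and the hepatocyte median -0.756 without elemental control 6, with 0 members past the threshold over the list alone in either case. In the TCA cycle list 4 of 20 genes were lower in casein controls, 19 over the list alone, and these 4 were the pyruvate dehydrogenase subunits Pdhb (2.37-fold), Dlat (2.16-fold), Pdha1 (2.08-fold) and Dld (1.66-fold). Of 22 cholesterol synthesis genes 2 were lower, Nsdhl (1.80-fold) and Acat2 (1.74-fold), and 11 over the list alone. In nuclear oxidative phosphorylation 1 of 42 was lower, Atp5d (1.56-fold), and 39 over the list alone (median -0.58; Cycs -0.92, SE 0.23). None of these 3 lists passed with an estimated correlation (adjusted p = 0.067, 0.074 and 0.074), while each passed fry (adjusted p = 0.012). The TCA cycle and oxidative phosphorylation scores were lower in casein controls by 0.717 and 0.55, with 5 of 6 below all elemental controls for each (exact permutation p = 0.00433, adjusted p = 0.0216 for each, n = 6 each). Fatty acid oxidation genes had 0 of 22 past the threshold and 16 lower over the list alone (Hadha -1.07, SE 0.28; adjusted p = 0.074 with an estimated correlation), and their score did not pass (exact permutation p = 0.0216, adjusted p = 0.0573, n = 6 each). Mitochondrially encoded transcripts had 0 of 8 past the threshold and 8 lower over the list alone (mt-Nd2 -0.93, SE 0.22), and passed with an estimated correlation (adjusted p = 0.049). Of 25 thermogenic genes Kcnk3 was lower (1.72-fold), and 10 were over the list alone (adjusted p = 0.18 with an estimated correlation). Ucp1 (log2 fold change -1.78, SE 0.85, adjusted p = 0.391), Lep (0.75, SE 0.64; -0.345 without casein control 5 and -0.0511 in limma voom), Asns (-0.20, SE 0.19) and Psat1 (0.00, SE 0.31) did not pass. With single libraries left out Asns ran from -0.331 (casein control 5) to -0.0903 (casein control 6). Psat1 ran from -0.379 (casein control 5) to 0.169 (elemental control 5). The count of 100 was 2 when only the control groups were fitted, where 1 of the 28 lipogenic genes was lower over all genes and 21 over the list alone. It was 0 in edgeR within the control libraries without lymph node transcripts, 2 against 2 (950 at an unadjusted p under 0.05), 177 within those with them and 313 with lymph node presence as a term. It was 30, 202, 24, 194 and 53 without elemental controls 1, 2, 3, 4 and 6, 66 without elemental MR 1 or 2, and 35, 55, 177 and 33 without casein controls 1, 4, 5 and 6.

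No gene passed between the MR diets in edgeR, oxidized casein against elemental amino acids, with 1060 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.176. Independent genes without any difference would give 758.8, and the median over other splits of these libraries was 349. DESeq2 called 12 genes and limma voom 202. The lipogenic list had a median log2 fold change of -0.23 and Fasn of -0.45 (SE 0.25), Scd1 of 0.32 (SE 0.20). Thermogenic genes had a median of -0.65, with Slc25a20 at -0.66 (SE 0.22) and Ucp1 at -0.83 (SE 0.83), white adipocyte genes of 0.32 with Cfd at 0.90 (SE 0.26), and extracellular matrix genes of 0.53 with Thbs2, a thrombospondin, at 1.58 (SE 0.35). Gstt1, a glutathione transferase, had a log2 fold change of 0.83 (SE 0.20), Lep of 0.93 (SE 0.65), Asns of 0.09 (SE 0.19) and Psat1 of 0.29 (SE 0.31). With lymph node presence as a term Ucp1 was at 0.0998, Fasn at -0.285, Scd1 at 0.166, Lep at 0.0706, Asns at -0.206 and Psat1 at -0.207, and none passed. Of the 32 lists 20 passed camera at the preset correlation, and 0 passed with an estimated correlation or fry. Lymph node transcripts were present in 5 elemental MR and 2 oxidized casein MR libraries. Among these, white adipocyte scores were 8.539 and 8.614 on oxidized casein, within the range of 8.355 to 8.89 on elemental amino acids. Their extracellular matrix scores were 5.811 and 5.896 on oxidized casein, within the range of 5.459 to 6.057 on elemental amino acids. Marker medians were -0.897 for B cells, -0.768 for T cells, -1.57 for skeletal muscle (1.35 without elemental MR 2) and 0.586 for adipose progenitors.

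In the GENCODE M21 annotation of GRCm38, Ucp1 (ENSMUSG00000031710) lies on chromosome 8 from 83290352 to 83298452, Slc25a34 (ENSMUSG00000040740) on chromosome 4 from 141618824 to 141623821, Dhrs9 (ENSMUSG00000027068) on chromosome 2 from 69380445 to 69404533 and Lgr6 (ENSMUSG00000042793) on chromosome 1 from 134983301 to 135105276. Fasn (ENSMUSG00000025153) lies on chromosome 11 from 120805846 to 120824547, Acly (ENSMUSG00000020917) on chromosome 11 from 100476353 to 100528000, Igfbp4 (ENSMUSG00000017493) on chromosome 11 from 99041244 to 99054392, Slc2a5 (ENSMUSG00000028976) on chromosome 4 from 150119283 to 150144169 and Lep (ENSMUSG00000059201) on chromosome 6 from 29060220 to 29073877. All are protein-coding genes, and counts sum reads over each gene, which 3′ libraries take mainly from its last exon and 3′ UTR.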

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

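The tests of lymph node content, skeletal muscle and stromal share against the oxidative phosphorylation pattern, and of lymph node content against the lipogenic pattern, were chosen after the results were seen.

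The higher level of oxidative phosphorylation genes with MR had a list median log2 fold change of 0.466 on elemental amino acids, where 0 of 42 passed over all genes in edgeR and 39 over the list alone, and of 0.754 on casein. The tables argue against lymph node content as its whole cause, since the medians were 0.443 and 0.811 with lymph node presence as a term, and 40 and 41 of 42 members were then higher over the list alone, although on elemental amino acids the median within the libraries with lymph node transcripts was 0.371 with 0 members past the threshold over the list alone. They argue against skeletal muscle in the same way, with medians of 0.452 and 0.779 and 39 and 41 members with the muscle score as covariate. A smaller share of stromal cells stays open on elemental amino acids. There the MR difference of this list's score minus that of the white adipocyte list was 0.701 (exact permutation p = 0.0714, n = 6 each). On casein this difference was 0.587 (exact permutation p = 0.0909, n = 6 each). These 2 tests ignored lymph node content. The white adipocyte score was at least 9.191 in every library without lymph node transcripts and at most 9.01 in every library with them. The white adipocyte score itself was 8.74 with MR and 8.95 in controls on elemental amino acids (exact permutation p = 0.361). On casein it was 9.11 with MR and 8.92 in controls (exact permutation p = 0.528). There 4 of 6 controls and 2 of 6 MR libraries held lymph node transcripts. With them, this score was 8.539 and 8.614 with MR and 8.246 to 8.944 in controls. The oxidative phosphorylation score was 8.348 and 8.433 against 7.166 to 7.863. Without them, the white adipocyte values were 9.191 to 9.536 against 9.482 and 9.821. The oxidative phosphorylation values were 8.179 to 8.737 against 7.668 and 7.7. On casein these values argue against a larger share of adipocytes, as read from the white adipocyte score, as the whole cause. An effect of MR within adipocytes, which the diets name, is an untested candidate explanation. On elemental amino acids the tests do not separate it from a larger share of adipocytes.

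Lipogenic genes were lower in casein controls than in elemental controls, with a median of -0.937 over 28 members. Lymph node content as the whole cause is argued against by a median of -1.14 within the libraries with lymph node transcripts, 4 against 4, where 27 of 28 were lower over the list alone. Liver RNA in the elemental controls is argued against by a median of -0.816 with the hepatocyte score as covariate, with 21 of 28 lower. Library size is argued against because 15 of the 15 called members were called after all libraries were thinned to the smallest. The protein source, which the diets name, remains an open and untested explanation, and so does any batch that the labels do not give.

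Alb stood at 5610 CPM in elemental control 6 against a median of 439 CPM over the 24 libraries. Of the 19 tested hepatocyte markers 18 had their highest level there, the exception being Cyp2e1, which was highest in casein control 3. An error in counting a single gene is argued against by 17 of the 18 markers other than Alb. The values are consistent with some liver RNA in that library, as a hypothesis, and how it would have entered was not tested. No biological explanation was tested.

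The MR effect on the lipogenic list was larger on casein by a median of 0.801 on the log2 scale, which passed camera with an estimated correlation (adjusted p = 0.02). Of its 28 members 0 passed over all genes in edgeR and 15 over the list alone, and the exact permutation test of its score did not pass (p = 0.0239, adjusted p = 0.0598). Its scores were 8.27 and 7.24 in elemental and casein controls and 8.30 and 8.10 in the MR groups, so the gap lay mainly between the controls. Casein was oxidized in the MR diet and intact in its control, so oxidation of casein cannot be separated from MR in this difference.

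Of 508 diet groups of 6 libraries examined over 127 measures, 34 had a library far from the other 5, where chance gives about 1 in 20. The values that follow are log2 CPM, with list scores as means of the members. Oxidized casein MR 6 was low in Slc25a34 (2.74), Gk (3.88), Ucp1 (6.64) and Lgr6 (0.126) and high in Slc27a1 (6.46). Oxidized casein MR 1 was high in Idh3a (9.11), Cox4i1 (9.61), Insig1 (7.46), the lipogenic score (8.58) and the fatty acid oxidation score (8.05). Casein control 6 was low in Pcx (5.83), Uqcrb (7.30), Atp5d (7.20), Pnpla2 (9.57), Slc25a1 (6.67), the lipogenic score (6.58) and the oxidative phosphorylation score (7.17). Casein control 5 was high in Nedd9 (7.20), the cholesterol synthesis score (4.57) and the immediate early score (4.14), and casein control 3 in Gk (4.99). Elemental control 5 was high in Adgre1 (4.41) and the macrophage score (4.66), and elemental control 3 low in Ntm (1.4). Elemental MR 4 was high in Gsta4 (5.66), Acly (10.9) and Acat2 (7.61) and low in Thbs2 (1.85). Elemental MR 1 was low in Pnpla2 (10.6), Abhd5 (6.60) and Gstt1 (5.16), and elemental MR 3 low in Gclm (4.47). Elemental MR 2, the elemental MR library without lymph node transcripts, was low in the B cell score (1.75) and the T cell score (0.785).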

How the results depend on the processing

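The tests with lymph node presence as a term, those within libraries with or without lymph node transcripts, that without both muscle-rich libraries and that without mitochondrial genes and Gm42418 were chosen after the data were seen. Counts are given in the order MR on elemental amino acids (37), MR on casein (579), casein against elemental control (100) and the overlap of the MR calls (30). Where a count moved, the cause was not tested unless stated. Other size factors, upper-quartile scaling, no filter, the stricter filter, the muscle score as covariate and removal of mitochondrial genes and Gm42418 kept each count within 1.5 times. DESeq2 gave 213, 915, 411 and 142, and called 36 of the 37, 575 of the 579 and 97 of the 100 genes. It gave 2 for the interaction and 12 between the MR diets, where edgeR gave 0. Limma voom with sample weights gave 118, 1968, 182 and 76, and 202 between the MR diets, and 59.5% of its casein MR calls were higher, against 87.9% in edgeR. The shares of higher genes in the MR comparisons were 57% and 63.4% with the lymph node score as covariate, and 71.8% of the DESeq2 calls on elemental amino acids were higher, against 89.2% in edgeR. Fitting only the 2 groups compared gave 23, 339, 2 and 11. Fewer libraries then estimate the dispersions, which was not tested as the reason. With the lymph node score as covariate the counts were 200, 1093, 361 and 147, and 1 between the MR diets. An adjusted p under 0.01, a stricter threshold by construction, gave 1, 186, 16 and 1. Lymph node presence as a term gave 166, 1120, 313 and 133. Fewer libraries were fitted within those with lymph node transcripts (5, 5, 177 and 2) and within those without (0, 172, 0 and 0, in edgeR, where 1013 and 950 genes had an unadjusted p under 0.05 for MR on elemental amino acids and for the controls). Without lymph node transcripts there was 1 elemental MR library, also rich in muscle, against 2 controls, and the fit assumes that it varies like the other groups, so the first 0 and the overlap of 0 say nothing about stability. The controls were 2 against 2. Of the 172, 43.6% were higher. Without both muscle-rich libraries the counts were 8, 644, 170 and 8. Counting genes called on one protein source with an unadjusted p under 0.05 on the other gave an overlap of 395, a looser criterion by construction. Pearson's r of the MR fold changes between protein sources was -0.0181 in DESeq2 over 16821 genes, including genes removed by the filter, and 0.24 over the 15176 genes edgeR tested, while Spearman's rho was 0.209 and 0.248. The fatty acid oxidation list changed direction in the interaction within the libraries without lymph node transcripts, where 1 library stands for elemental MR (camera adjusted p = 0.81). In that setting 8 of 32 lists had the other direction in the interaction, 5 for MR on casein and 9 between the MR diets. With lymph node presence as a term these counts were 7, 2 and 9. With an estimated correlation camera lost 12, 11, 19, 11 and 20 list calls in the 5 comparisons.

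Leaving out single libraries gave 7 to 252 genes for MR on elemental amino acids (7 without elemental control 5 or elemental MR 6, 8 without elemental control 2 or 4 or elemental MR 4, 15 without elemental control 6, 57 without casein control 6, 252 without elemental control 1). It gave 316 to 825 for MR on casein (316, 350 and 377 without casein control 6, oxidized casein MR 1 and casein control 1), and 24 to 202 between the controls. It gave 0 to 1 between the MR diets (1 without oxidized casein MR 3), and 7 to 180 for the overlap (180 without elemental control 1, 14 without elemental control 6, 8 without elemental control 2 or 4 or elemental MR 4, 7 without elemental control 5 or elemental MR 6). The interaction count was 0 in edgeR under each. Slc25a34 passed under each left-out library in both MR comparisons. Of 137 gene results, 120 kept their side of the threshold in DESeq2 and 17 newly passed, and these counts were 122 and 11 in limma voom, where 4 no longer passed. With only the 2 groups fitted 45 no longer passed, within libraries with lymph node transcripts 62 and within those without 70. No gene that passed changed direction in these settings, while some that did not pass changed sign, such as Lep between the controls. Thinned to the reads of the smallest library, the 3 comparisons called 27, 569 and 100 genes, so fewer reads lowered the count for MR on elemental amino acids. No paired analysis was possible because the replicate numbers follow the order of the samples, each library is a separate mouse, and the labels give only mouse numbers that pair no mice between diets.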

Other observations

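The test of thermogenic genes against lymph node transcripts within diets, with its companion tests, was chosen after the data were seen, as were the splits with lymph node presence as a term.

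With MR on casein, genes that release and take up fatty acids rose in 3 of 15 cases, namely Pnpla2, adipose triglyceride lipase (1.43-fold), its activator Abhd5 (1.52-fold) and the fatty acid transporter Slc27a1 (1.62-fold). The list had an adjusted p = 0.69 with an estimated correlation. Of 21 insulin signalling genes Slc2a4, Pck1 and the glycogen-targeting subunit Ppp1r3c (2.05-fold) rose, with 6 higher and 2 lower over the list alone (adjusted p = 0.15 with an estimated correlation). Of 36 ATF4 targets Gars, glycyl-tRNA synthetase, rose (1.42-fold). Of 35 methionine and one-carbon genes Ahcyl1 (1.61-fold) and Msra, a methionine sulfoxide reductase (1.39-fold), rose. Of 27 glutathione and NRF2 targets Gsta4 rose (1.51-fold), with 8 higher over the list alone (adjusted p = 0.51 for that list with an estimated correlation). The methionine list had a median of -0.00647 and a mean of 0.0165. The endothelial list held Fabp5, a fatty acid binding protein also made by adipocytes, which rose with MR on casein (1.71-fold) and was lower in casein than in elemental controls (1.85-fold). Plvap, an endothelial diaphragm protein, was lower with MR on casein (1.51-fold). Cyp2e1 was the 1 member of the hepatocyte list lower with MR on casein. It was also the 1 member not highest in elemental control 6 (355.9 CPM, against 420.6 CPM in casein control 3). In the control comparison Gclm, which makes glutathione, was lower (1.63-fold, 1 of 27). In the same comparison 4 methionine genes were lower over the list alone (0 of 35 over all genes; adjusted p = 0.31 for both lists with an estimated correlation).

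On elemental amino acids, 0 members passed over all genes in edgeR in the lipolysis (median 0.09), methionine (-0.09), glutathione (-0.02), insulin (0.10), cholesterol (-0.08), ER stress (-0.02), interferon (0.17), proliferation (0.00), circadian (-0.11) and immediate early (-0.16) lists, and in any marker list. With MR on casein the same was true of the cholesterol (0.17), ER stress (0.00), interferon (-0.01), proliferation (-0.37) and immediate early (-0.26) lists and of the marker lists other than the hepatocyte and endothelial ones. Medians of marker lists for MR on elemental amino acids and on casein were 0.18 and -1.06 for B cells, 0.20 and -0.75 for T cells, and -1.03 and 0.82 for skeletal muscle. They were -0.92 and 0.35 for keratinocytes, -1.69 and -0.21 for ductal epithelium, and -1.54 and 0.06 for hepatocytes. They were -0.34 and -0.21 for smooth muscle, -0.59 and 0.74 for red blood cells, -0.38 and -0.12 for nerve, and -0.28 and -0.44 for granulocytes and mast cells. The elemental muscle median was 2.64 without elemental control 2 and -3.89 without elemental MR 2, and without elemental control 6 the hepatocyte median was -0.148 and the keratinocyte median -0.269. The elemental medians of B cells, T cells, nerve, and granulocytes and mast cells, and the casein medians of ductal epithelium, hepatocytes and nerve, changed sign without 1 library or another. Across left-out libraries the casein medians ran from -1.79 to -0.756 for B cells, -1.37 to -0.377 for T cells and 0.364 to 1.15 for skeletal muscle. They ran from 0.119 to 0.469 for keratinocytes and from 0.414 to 0.875 for red blood cells. None of these marker lists passed with an estimated correlation in either comparison (smallest adjusted p = 0.14).

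Thermogenic genes varied among libraries of the same diet, and a candidate explanation is the region of the pad sampled, as marked by lymph node transcripts. Within diets the thermogenic score was higher in the libraries with lymph node transcripts, by 1 in elemental controls, 0.193 in elemental MR, 0.978 in casein controls and 0.524 in oxidized casein MR (exact permutation within diets, p = 0.00173, adjusted p = 0.00346 over 4 tests, 20250 arrangements). For Ucp1 the differences were 3.27, 0.59, 3.53 and 1.21 in log2 CPM (exact permutation p = 0.000642, adjusted p = 0.00257). The oxidative phosphorylation score (exact permutation p = 0.344, adjusted p = 0.459) and the lipogenic score (exact permutation p = 0.559, adjusted p = 0.559) did not pass. The labels do not say which part of the pad was taken.

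Each comparison was repeated on 100 splits of its libraries, the real one included. Chance was called unlikely where fewer than 5 splits gave as many genes, without adjustment for the number of such tests. For MR on elemental amino acids 1 split gave as many genes, the real one (37 genes, highest other 1), so chance is unlikely. For MR on casein 2 splits did (579, highest other 5251), so chance is unlikely but not excluded. The split with 5251 genes parted all 6 libraries with lymph node transcripts from the 6 without, which points to a structure of the samples. With lymph node presence as a term 1 split did (1120, highest other 67), so chance is unlikely there too. For the controls 5 splits gave as many genes (100, highest other 861, with 2 against 6 lymph node libraries), so chance cannot be excluded. The other 4 splits were uneven in lymph node libraries, unlike the real one with 4 against 4. They gave 188 genes (6 against 2), 733 (5 against 3), and 536 and 861 (2 against 6 in each). With lymph node presence as a term, which was chosen after the data were seen, 2 splits gave as many genes (313, highest other 844). Another split still gave more genes than the real one, so chance is less likely there but not excluded. For genes at an unadjusted p under 0.05, 52 splits gave as many in the interaction (506, highest other 4208) and 12 between the MR diets (1060, highest other 3417), so chance cannot be excluded for either.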
